A study of Mus musculus with 24 samples.

How the data were processed

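Gene expression was measured in R1 cells, a mouse embryonic stem (ES) cell line, on 24 Agilent 2-colour arrays. The cells carried a lentiviral short hairpin RNA: a non-targeting control (shNTC), 1 of 2 hairpins against Cdk8, or 1 of 2 hairpins against Med12. Per the labels, RNA came from cells grown for 8 or 13 days after infection. There were 3 biological replicates of each of 8 groups: shNTC, shCdk8-1 and shCdk8-2 on day 8, and those groups plus shMed12-1 and shMed12-2 on day 13. The labels call the replicates biological but do not say whether the cultures or infections were separate, so p-values measure the spread between these arrays. Per the labels' protocols, Cy5 holds the RNA of the cells and Cy3 a universal mouse reference RNA made from a mixture of mouse cell lines, on every array without dye swaps, and 750 ng of labelled cRNA was hybridised.

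Per the submitters' processing notes, spots were quantified with Agilent Feature Extraction 10.7. The deposited scanner files give the median pixel intensity of each spot and of its local background in both channels, per the file headers, with no normalization. The same deposited files hold a log10 ratio of Cy5 over Cy3 made by Feature Extraction after its own background subtraction and dye normalization, per the file headers. The authors' deposited value table holds log2 ratios of Cy5 over Cy3. Its scale, direction and probe identity were settled by setting each column against the scanner log ratio of the same array: the slope was 1.00 on every array over 41174 probes. Column medians ran from -0.0045 to 0.12, so the columns were not centred on 0, and between 3384 and 10357 values per column were blank for a reason that is not given in the sources used here.

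Each array held 45018 spots, of which 1639 were controls, and 41174 probes. Probes were named by matching their RefSeq accession, without version, to a RefSeq gene table of assembly GRCm38.p6, used for names alone. A symbol was found for 22951 probes and none for 18223, which kept the name in the files. Probes for Nanog, Med13 and Med12l were not matched, and those genes are not reported here. Spot and background intensities were corrected with normexp (offset 50), fitted on all spots of an array. Log2 ratios of Cy5 over Cy3 were then normalized by loess within each array, with weight 0 for control spots and for spots with an outlier mark, which were left out afterwards (median 334.5 per array). No spot was saturated. Arrays were not normalized against each other. Spots of one probe were averaged. Probes were kept that were well above background in Cy5 on all 3 arrays of at least 1 group, which gave 28304 probes. Of these, 63 with a missing value were then dropped. Where a gene had several kept probes (4805 genes), the probe with the highest mean brightness stood for it. Among genes with several called probes, the probes disagreed in direction for 31 of 352, 23 of 305, 8 of 251, 4 of 270, 11 of 634 and 3 of 459 genes in the 6 hairpin comparisons, from shCdk8-1 on day 8 to shMed12-2. That left 22394 genes, 13731 of them with a symbol. The plan named mean spot intensities and a gene name column, which the files do not hold, and median intensities and accessions took their place.

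Linear models were fitted with limma 3.58.1 in R 4.3.3 (files read with data.table, version 1.17.8), with all 24 arrays in 1 fit of 8 group means (16 residual degrees of freedom) and a moderated two-sided test. P-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called changed at an adjusted p under 0.05. Each hairpin was compared with shNTC of the same day. A gene changed with both hairpins when it was called with each in the same direction, and its fold change is the mean over both hairpins (6 knockdown arrays against 3 shNTC arrays). Cdk8 was also set against Med12 knockdown on day 13, and the Cdk8 effect on day 13 against that on day 8. Gene lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with a correlation estimated from the data, with adjustment over 22 lists in each comparison. In the list counts, a member had to be called with both hairpins.

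The groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Cdk8, Med12 and the other kinase module genes, then Pou5f1, Nanog, Sox2, Klf4, Zfp42, Esrrb and Myc. It adds, for each knockdown and day, the 10 highest and 10 lowest fold changes among genes with a symbol that changed with both hairpins and whose knockdown arrays all lay beyond all shNTC arrays of that day. Next come the 5 highest and 5 lowest genes of the remaining comparisons. Last, it takes up to 4 called members of each list, or up to 2 as values where none was called. Some genes that the rule takes are not reported here.

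The number of arrays limits the precision. Between 48.9% and 76.1% of the spots on an array were well above background in Cy5. The procedure was tested on simulated data with known changes, drawn for shCdk8-1 against shNTC on day 8 over 22394 genes: it recovered 17 of 68 genes changed by 0.25 on the log2 scale, 55 of 66 changed by 0.5 and 65 of 65 changed by 1. The simulation also shifted the 37 measured endoderm genes by -0.3, and calls of these counted as true. Of its 150 calls 5 were false. Its noise was independent between arrays, without slide or array effects, so this share need not hold for the real arrays. No pair of arrays held identical values. Because comparisons share shNTC arrays, unchanged groups were simulated against shared controls 50 times.

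Alternatives covered the background correction, the normalization within and between arrays, the Cy5 channel alone, Feature Extraction's log ratios, the authors' value table, the probe filter, the probes of a gene, the arrays in the fit, slide and replicate number as blocks, and leaving out each array. After the data were seen, 2 more were added because log ratios on 2 arrays were pulled toward 0: leaving out both arrays, and fitting the background model without spots that carry an outlier mark, with every spot still corrected (called the refitted background here). The planned values stand as the main ones, with some of the values after the refitted background beside them.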

Results

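The series asked what loss of Cdk8 or of Med12 does to gene expression in mouse ES cells. Both encode parts of the kinase module of Mediator, the complex that links transcription factors to RNA polymerase II: Cdk8 is its cyclin-dependent kinase and Med12 the subunit that activates the kinase. The data are log2 ratios of each sample to a common reference RNA on 24 arrays, in 8 groups of 3 arrays each. Fold changes below are on the log2 scale with the standard error of the fit in parentheses, and genes are named by symbol.

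The targeted transcripts were lower wherever they were targeted. Cdk8 fell by 0.71 with shCdk8-1 (SE 0.07, adjusted p = 1.5e-06) and by 0.31 with shCdk8-2 (adjusted p = 0.0075) on day 8. On day 13 it fell by 0.95 (adjusted p = 5.0e-08) and by 0.64 (adjusted p = 1.1e-05). Med12 fell by 1.00 with shMed12-1 (adjusted p = 9.5e-09) and by 0.88 with shMed12-2 (adjusted p = 6.6e-08). In ratios to the reference, Cdk8 was at -0.51 ± 0.08 (SD, n = 3) in shNTC cells on day 8, against -1.21 ± 0.14 and -0.82 ± 0.08 with the 2 hairpins. On day 13 the values were -0.53 ± 0.07 in shNTC cells, against -1.48 ± 0.10 and -1.17 ± 0.10. Med12 was at -0.99 ± 0.11 in shNTC cells on day 13, against -1.99 ± 0.05 and -1.87 ± 0.12. Every knockdown array lay below every shNTC array of its day. A further probe for Cdk8 gave -0.30 and -0.39 on day 8 and -0.43 and -0.34 on day 13, and one for Med12 gave -0.85 with both hairpins. On the slides that held both groups, Cdk8 differed from shNTC by -0.16 with shCdk8-2 on day 8 and by -0.50 on day 13, and Med12 with shMed12-2 by -0.96 and -1.03. With median centring in place of loess, the day 8 fall with shCdk8-2 was -0.35 and no longer called.

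**Figure D1:**
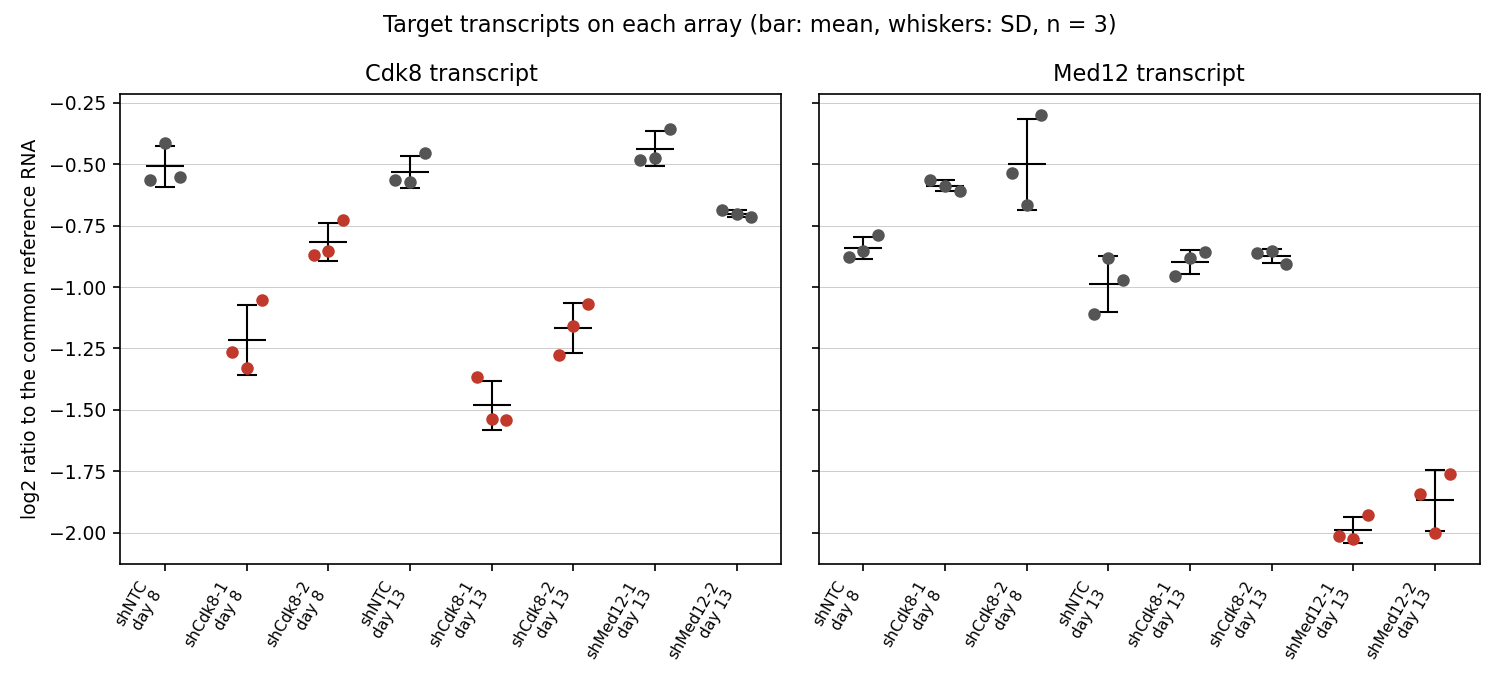
Log2 ratio of the Cdk8 (left) and Med12 (right) transcript to the common reference RNA on each of the 24 arrays, by group. Points are arrays (red where the gene was targeted), bars the mean and whiskers the SD of 3 arrays, and every red point lies below every shNTC point of its day.

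Of the other kinase module genes, Med12 rose by 0.25 and 0.34 with the 2 Cdk8 hairpins on day 8 and differed by 0.09 and 0.12 on day 13, not called. Cdk8 differed by 0.09 and -0.17 with the Med12 hairpins, not called. Cdk19, the paralog of Cdk8, cyclin C (Ccnc) and Med13l were not called with any hairpin, with means over both hairpins between -0.19 and 0.09. For Ccnc on day 8 the probe used gave 0.04 and 0.14 with the Cdk8 hairpins, but a further probe gave -0.38 and -0.11. The list of Mediator and its kinase module had a median of -0.04 with Cdk8 knockdown on day 8, 0.00 on day 13 and -0.02 with Med12 knockdown, not called.

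Among pluripotency factors, Klf4 fell by 1.01 (SE 0.05) with Med12 knockdown, in both hairpins (-0.60 and -1.43), and by 0.20 with Cdk8 knockdown on day 13, not called with slide as a block (adjusted p = 0.098). It was not called with Cdk8 knockdown on day 8 (-0.10). Pou5f1, the gene of Oct4, was not called in both hairpins in any comparison: its means were -0.61 and -0.30 with Cdk8 knockdown on days 8 and 13 and -0.59 with Med12 knockdown. With slide as a block these Pou5f1 means were -0.42, 0.07 and -0.25. Sox2 was at -0.29, -0.12 and -0.82 and Myc at -0.07, 0.18 and -0.16, not called with both hairpins. The Myc mean on day 13 joins -0.13 with shCdk8-1, not called, and 0.48 with shCdk8-2, called. Other calls came with a single hairpin: Pou5f1 fell by 1.00 with shCdk8-1 on day 8, and Pou5f1 (-1.12), Zfp42 (-0.91), Esrrb (-0.96) and Myc (-0.22) fell with shMed12-1. Zfp42, at -0.32, -0.21 and -0.76, and Esrrb, at -0.27, -0.24 and -0.77, were not called with both hairpins, but with Med12 knockdown both were called after the refitted background (-0.51 and -0.57). These genes are bright in ES cells against the reference, and on 2 arrays, shCdk8-1 day 8 replicate 1 and shMed12-1 day 13 replicate 3, the log ratios of such genes were pulled toward 0, with slopes on the other replicates of their group of 0.79 and 0.79 against 0.97 to 1.12 on the other 22 arrays. After the refitted background the slopes were 0.97 and 1.01, and the Med12 values of Pou5f1 and Sox2 -0.42 and -0.52. For Cdk8 knockdown on day 8 it gave -0.43 for Pou5f1, 0.03 for Sox2, -0.07 for Zfp42 and -0.11 for Esrrb, and without both arrays Sox2 was at 0.09 and Zfp42 at -0.06.

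After 8 days of Cdk8 knockdown, endoderm genes were lower. Sox7 fell by 1.15 (SE 0.08) and Gata6 by 1.00 (SE 0.12), 2 transcription factors of primitive endoderm. The simple epithelial keratins Krt8 and Krt18 fell by 0.85 (SE 0.05) and 0.84 (SE 0.04). All had adjusted p from 2.5e-10 to 1.4e-05. The hairpins differed in size: Gata6 stood at -0.62 with shCdk8-1 and -1.38 with shCdk8-2, and Krt8 at -0.53 and -1.16. Besides Sox7 and Gata6, the 10 lowest genes held Khdc3 (-1.24), a gene of the oocyte's maternal complex, and F3 (-1.10), which encodes tissue factor. They also held the WNT antagonist Dkk1 (-1.05), Slc52a3 (-1.05), a riboflavin transporter, Prss23 (-0.95), Gjb5 (-0.93), the histone gene H2bc4 (-0.92) and Htra1 (-0.90). Among the 10 highest genes were Sall2 (1.05, SE 0.07), a zinc finger factor, Btbd17 (1.03), Acss1 (1.00), the acetyl-CoA synthetase of mitochondria, and Hes6 (0.95). Napsa (0.90), Cplx2 (0.89), the Notch ligand Dll1 (0.86), the kinase Pim2 (0.85) and Enpp2 (0.83), which encodes autotaxin, were others of them.

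Of 22394 genes, 3775 changed with shCdk8-1 on day 8 (1934 higher, 1841 lower) and 3136 with shCdk8-2 (1654 higher, 1482 lower), of which 56 and 37 changed at least 2-fold. With the refitted background 4840 and 4562 changed. Both hairpins changed 1142 genes in the same direction, 623 higher and 519 lower, and 115 genes in opposite directions. The shared count was 1725 after the refitted background, 310 with slide as a block, 90 with median centring, 497 with only the groups compared and 754 without shNTC replicate 2, and the Cy5 channel alone gave 795 higher and 837 lower. With slide as a block, all 20 highest and lowest genes kept their direction and 19 their call, Dkk1 being lost (adjusted p = 0.058). In the sample channel alone Cplx2 stood at -0.018 and was not called, and further probes differed from the ones used for Cplx2 (0.04), Prss23 (0.13), Slc52a3 (-0.49) and Gata6 (-0.24 and -0.18).

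Among the gene lists, 11 of 37 endoderm markers fell and 0 rose with both Cdk8 hairpins on day 8 (12 and 0 adjusted over the list alone). Their median was -0.41 (adjusted p = 5.7e-13, and adjusted p = 3.4e-05 with an estimated correlation), and -0.41 with slide as a block. Stress genes of the unfolded protein and amino acid response rose, 7 of 46 with 0 lower (7 and 0 adjusted over the list alone), with a median of 0.15 (adjusted p = 1.3e-08, and adjusted p = 0.059 with an estimated correlation). They included Herpud1 (0.83), a gene of protein degradation at the endoplasmic reticulum, the glycine transporter Slc6a9 (0.57), Vldlr (0.46) and Xbp1 (0.36), a transcription factor of the unfolded protein response. Markers of the 2-cell-like state fell, with a median of -0.37 over 15 (adjusted p = 2.8e-06, and adjusted p = 0.12 with an estimated correlation). Of these, P4ha2 (-0.74), a collagen prolyl hydroxylase, and Tcstv1 (-0.63) passed with both hairpins, 2 lower and 0 higher (3 and 0 adjusted over the list alone), but Tcstv1 was not called with slide as a block (adjusted p = 0.15). Trophectoderm markers fell with a median of -0.26 over 20 (adjusted p = 0.0025, and adjusted p = 0.23 with an estimated correlation). The 2 members that passed with both hairpins were Krt8 and Krt18, which are also on the endoderm list (2 lower and 0 higher in both counts, over all genes and adjusted over the list alone).

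Genes of naive and general pluripotency fell with a median of -0.23 over 37 (adjusted p = 0.0050, and adjusted p = 0.55 with an estimated correlation), but only 1 passed with both hairpins, the T-box gene Tbx3 at -0.55 (also 1 adjusted over the list alone), and the median was -0.10 after the refitted background. Fibroblast and feeder markers had a median of -0.04 over 37 (adjusted p = 0.028, and adjusted p = 0.57 with an estimated correlation): 8 fell and 0 rose (8 and 0 adjusted over the list alone), among them Tagln (-0.69), an actin-binding protein of smooth muscle, S100a6 (-0.66) and Ccn2 (-0.54). The median turned to 0.01 with median centring in place of loess. Immediate early genes had a median of -0.06 over 37 (adjusted p = 0.029, and adjusted p = 0.55 with an estimated correlation), with 7 lower, such as Phlda1 (-0.56), Nr4a1 (-0.50) and Hbegf (-0.50), and 2 higher (8 and 4 adjusted over the list alone). Interferon response genes had a median of 0.17 over 41 (adjusted p = 7.1e-04, and adjusted p = 0.55 with an estimated correlation): the proteasome gene Psmb8 (0.74), Gbp2 (0.62) and Irgm1 (0.55) were among 4 that rose, and Ddx58 (-0.60, but -0.09 with a further probe), a sensor of viral RNA, was the 1 that fell (4 and 1 adjusted over the list alone). With slide as a block the interferon and immediate early lists were no longer called, with medians of 0.04 and -0.065. That fit gave medians of 0.12 for unfolded protein stress, -0.43 for the 2-cell-like state, -0.12 for trophectoderm, -0.21 for naive pluripotency and -0.083 for fibroblast markers.

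The stress list (adjusted p = 7.7e-04 with an estimated correlation) and the 2-cell-like and trophectoderm lists (adjusted p = 0.025 with an estimated correlation for both) were called with an estimated correlation too after the refitted background.

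The remaining lists were not called on day 8, but 3 of them were after the refitted background: primed (median 0.30), mesoderm (-0.07) and neural genes (0.05). Their planned medians were 0.20 for primed (epiblast) genes, where Lef1 rose by 0.64, and -0.11 for mesoderm, where Bmp4 fell by 0.64. Medians were 0.01 for neural genes, although Nes rose by 0.59, 0.00 for WNT targets, where 5 rose and 2 fell, and -0.03 for TGF-beta, NODAL and BMP genes, where 2 rose and 6 fell. They were -0.03 for MYC targets, 0.02 for p53 targets, 0.05 for hypoxia, 0.05 for cholesterol synthesis, -0.03 for cell cycle genes, -0.13 for germ line genes and 0.08 for HOX genes. Imprinted genes had a median of 0.04, although the growth factor gene Igf2 fell by 0.89 (SE 0.04; -0.58 with shCdk8-1 and -1.20 with shCdk8-2).

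After 13 days of Cdk8 knockdown, Thbs1, which encodes the matrix protein thrombospondin 1, rose by 1.21 (SE 0.12), the smooth muscle actin gene Acta2 by 0.98 (SE 0.05), the cardiac actin gene Actc1 by 0.92 (SE 0.09) and Cav1, a coat protein of caveolae, by 0.90 (SE 0.10), with adjusted p from 1.0e-09 to 5.5e-06. The other genes among the 10 highest were the interferon-induced GTPase gene Gbp2b (1.05), Skor1 (1.01), Pmp22 (0.95), Kctd12b (0.89), Anxa1 (0.87) and Fgfbp1 (0.85). Khdc3 was lowest, at -1.32 (SE 0.21), followed by Plac8 (-1.13), Ly6g6e (-1.13), Rpl39l (-0.93), a ribosomal protein gene with a paralog on the X chromosome, and Hkdc1 (-0.92). Ldhc (-0.90), the lactate dehydrogenase of testis, Cpn1 (-0.87), the meiotic kinase Aurkc (-0.81) and Cdk8 itself (-0.79) were also among the 10 lowest.

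On day 13, 2822 genes changed with shCdk8-1 (1455 higher, 1367 lower) and 2587 with shCdk8-2 (1312 higher, 1275 lower), and 4138 and 3895 after the refitted background. At least 2-fold changes numbered 31 and 32. Both hairpins changed 945 genes in the same direction, 531 higher and 414 lower, and 87 in opposite directions. The shared count was 1558 after the refitted background, 279 with slide as a block, 49 with median centring (14 higher, 35 lower) and 570 without shNTC replicate 1. More genes were lower than higher in the Cy5 channel alone too (471 higher, 727 lower), in Feature Extraction's log ratios (833 and 994) and in the authors' values (839 and 1002). All 20 highest and lowest genes kept their direction with slide as a block. By the test of the mean over both hairpins, 13 stayed under an adjusted p of 0.05. Skor1, Fgfbp1, Ly6g6e, Hkdc1, Ldhc and Cpn1 were among those that did not. Further probes gave 0.70 and 0.52 for Thbs1, 0.24 and 0.90 for Acta2 and 0.11 for Cav1.

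Fibroblast and feeder markers rose on day 13: 5 of 37 were higher and 0 lower (5 and 0 adjusted over the list alone), with Thbs1, Acta2, the intermediate filament gene Vim (0.73) and Tagln (0.70) at the top. Their median was 0.24 (adjusted p = 1.3e-06, and adjusted p = 0.27 with an estimated correlation). Interferon response genes rose, 7 of 41 with 0 lower (8 and 0 adjusted over the list alone), including Psmb8 (0.81), the chemokine gene Cxcl10 (0.77), Gbp2 (0.74) and Gbp3 (0.73). The median was 0.17 (adjusted p = 1.1e-04, and adjusted p = 0.47 with an estimated correlation). Immediate early genes rose, 6 of 37 with 1 lower (8 and 1 adjusted over the list alone), among them Ier5 (0.72), Ccn1 (0.56), the ERK phosphatase gene Dusp6 (0.53) and Klf6 (0.47). Here the median was 0.12 (adjusted p = 1.7e-04, and adjusted p = 0.27 with an estimated correlation). Imprinted genes rose, 5 of 29 with 0 lower (5 and 0 adjusted over the list alone), such as Mest (0.62), Cd81 (0.39), Igf2 (0.26) and Grb10 (0.26, but 0.06 with a further probe). Their median was 0.15 (adjusted p = 6.5e-04, and adjusted p = 0.17 with an estimated correlation).

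Trophectoderm markers rose, 4 of 20 with 0 lower (4 and 0 adjusted over the list alone): Gata3 (0.60), Id2 (0.58), Krt8 (0.39) and Krt18 (0.32). The median was 0.10 (adjusted p = 0.0086, and adjusted p = 0.27 with an estimated correlation). Neural genes rose with a median of 0.11 over 35 (adjusted p = 0.0037, and adjusted p = 0.27 with an estimated correlation), 2 of them in both hairpins, Meis2 (0.74) and Nes (0.69), with 0 lower (2 and 0 adjusted over the list alone). WNT targets had a median of 0.06 over 33 (adjusted p = 0.021, and adjusted p = 0.27 with an estimated correlation), with 6 higher, such as Sp8 (0.83), and 1 lower (6 and 1 adjusted over the list alone). HOX genes had a median of 0.17 over 26 (adjusted p = 0.0070, and adjusted p = 0.30 with an estimated correlation), where Hoxb2 (0.61) and Hoxc9 (0.55) rose and 0 fell (2 and 0 adjusted over the list alone). Cholesterol and fatty acid genes had a median of 0.05 over 42 (adjusted p = 0.0094, and adjusted p = 0.30 with an estimated correlation): Sqle (0.48), an enzyme of cholesterol synthesis, was among 3 that rose, and the cholesterol exporter gene Abcg1 (-0.71) the 1 that fell (5 and 1 adjusted over the list alone).

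Naive and general pluripotency genes fell with a median of -0.16 over 37 (adjusted p = 0.0086, and adjusted p = 0.56 with an estimated correlation). The 3 members that fell in both hairpins were Tbx3 (-0.74), Tcl1 (-0.53) and Klf4 (-0.20), with 0 higher (3 and 0 adjusted over the list alone). Genes of the 2-cell-like state fell with a median of -0.28 over 15 (adjusted p = 1.7e-04, and adjusted p = 0.27 with an estimated correlation), of which 1, P4ha2 (-0.56), passed with both hairpins (1 adjusted over the list alone). The mean over both hairpins was also tested with slide as a block. Of the list members named for day 13, Hoxc9, Tcl1, Cxcl10, Mest, Klf4 and Sox17 were then not called (adjusted p from 0.086 to 0.23). The medians of the 11 called lists with slide as a block were 0.25 for fibroblast markers, 0.13 for interferon, 0.071 for immediate early genes, 0.19 for imprinted genes, 0.059 for trophectoderm, 0.054 for neural genes, 0.017 for WNT targets, 0.16 for HOX genes, 0.086 for cholesterol, -0.17 for naive pluripotency and -0.32 for the 2-cell-like state. The endoderm list as a whole was not called (median -0.04, adjusted p = 0.33), although Gata6 (-0.77, but 0.02 and 0.04 with 2 further probes), Aqp8 (-0.69), Sox17 (-0.60) and Sox7 (-0.58) fell. On this day 6 lists were called with an estimated correlation after the refitted background, with adjusted p from 0.0054 to 0.041: imprinted, immediate early, neural, 2-cell-like, fibroblast and cholesterol genes. That background also brought calls at the preset correlation for primed (median 0.09) and germ line genes (-0.09). Medians of the other lists that were not called were 0.09 for primed genes, 0.06 for mesoderm, -0.05 for MYC targets, 0.02 for p53 targets, 0.03 for hypoxia, -0.02 for cell cycle, -0.09 for germ line and 0.04 for TGF-beta, NODAL and BMP genes. The median was -0.04 for unfolded protein and amino acid stress, where 5 rose and 3 fell, among them the stress factor gene Nupr1 (-0.56).

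With Med12 knockdown, keratin and actin genes were among the 10 highest. Krt18 rose by 2.00 (SE 0.04, adjusted p = 4.9e-17) and Krt8 by 1.77 (SE 0.05), and the smooth, skeletal and cardiac muscle actin genes Acta2, Acta1 and Actc1 rose by 1.94 (SE 0.05), 1.84 (SE 0.07) and 1.68 (SE 0.09). Krt20 (1.52), Krt7 (1.46), the LIM protein gene Fhl2 (1.43), Tagln (1.40) and Anxa1 (1.38) were the others among the 10 highest. The lowest gene was Inhbb, at -1.77 (SE 0.05), which encodes a subunit of activin B, followed by the lysine-degrading enzyme gene Aass (-1.49), Prmt8 (-1.46), Plk5 (-1.35), the laminin gene Lama1 (-1.34) and Igsf21 (-1.32). Col13a1 (-1.30), Zfyve28 (-1.28), Ceacam2 (-1.26) and Crtac1 (-1.24) completed the 10 lowest. Of Krt18 and Krt8 the reference channel was lower on the Med12 arrays (-0.53 and -0.41), and the sample channel alone gave 1.53 and 1.36.

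With shMed12-1, 5567 genes changed (2881 higher, 2686 lower) and with shMed12-2 3988 (2025 higher, 1963 lower), 186 and 123 of them at least 2-fold; after the refitted background 5991 and 5397 changed. Both hairpins changed 1927 genes in the same direction, 1072 higher and 855 lower, and 224 in opposite directions. The shared count was 2436 after the refitted background, 708 with slide as a block and 389 with median centring (138 higher, 251 lower). More genes were lower than higher in the Cy5 channel alone (871 higher, 1247 lower), in Feature Extraction's log ratios (1225 and 1470) and in the authors' values (1238 and 1484). The keratins differed in size between the hairpins: Krt7 rose by 2.39 with shMed12-1 and by 0.52 with shMed12-2, and Krt18 by 2.60 and 1.40. All 20 highest and lowest genes kept their call with slide as a block. Within the slides that held both groups, shMed12-2 differed from shNTC in Krt18 by 1.39 and 1.45, in Acta2 by 1.99 and 2.20 and in Inhbb by -2.27 on both. Further probes gave 0.55 and 1.87 for Acta2 and -0.38 for Inhbb.

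Trophectoderm markers rose with Med12 knockdown, 6 of 20 with 0 lower (6 and 0 adjusted over the list alone). Besides Krt18, Krt8 and Krt7 they included the homeobox gene Rhox6 (1.29). The median was 0.46 (adjusted p = 6.8e-09, and adjusted p = 0.027 with an estimated correlation), but 0.86 with shMed12-1 and 0.08 with shMed12-2. Fibroblast and feeder markers rose, 12 of 37 with 1 lower (13 and 1 adjusted over the list alone), with a median of 0.44 (adjusted p = 2.7e-11, and adjusted p = 0.20 with an estimated correlation). Acta2, Tagln, the galectin gene Lgals1 (1.13) and Ccn1 (1.04) led them. Immediate early genes rose, 13 of 37 with 0 lower (14 and 1 adjusted over the list alone), among them Ier5 (1.37), Phlda1 (0.91) and Jun (0.83), which encodes a subunit of AP-1. Their median was 0.18 (adjusted p = 2.7e-05, and adjusted p = 0.15 with an estimated correlation). Interferon response genes rose, 6 of 41 with 0 lower (7 and 0 adjusted over the list alone): Gbp3 (0.92), Gbp2 (0.83), B2m (0.78) and Irgm1 (0.77) were the largest. The median was 0.24 (adjusted p = 4.9e-05, and adjusted p = 0.57 with an estimated correlation).

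Cholesterol and fatty acid genes rose with a median of 0.10 over 42 (adjusted p = 0.0049, and adjusted p = 0.33 with an estimated correlation). Sc5d (0.54) and Mylip (0.53) were among 8 that rose, and Abcg1 (-0.86) was the 1 that fell (10 and 1 adjusted over the list alone). Genes of naive and general pluripotency fell with a median of -0.35 over 37 (adjusted p = 5.8e-09, and adjusted p = 0.26 with an estimated correlation). Klf4, Tcl1 (-0.67) and Mybl2 (-0.39) were the 3 that fell in both hairpins, with 0 higher (3 and 0 adjusted over the list alone). After the refitted background the median was -0.25, 11 fell, and adjusted p = 0.017 with an estimated correlation. MYC and ribosome biogenesis targets fell with a median of -0.08 over 66 (adjusted p = 1.8e-04, and adjusted p = 0.15 with an estimated correlation), 7 of them in both hairpins with 0 higher (7 and 0 adjusted over the list alone). The cyclin gene Ccnd2 (-0.97), Shmt1 (-0.41), Exosc5 (-0.40) and Shmt2 (-0.33) were the largest.

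With slide as a block these medians were 0.40 for trophectoderm, 0.44 for fibroblast markers, 0.21 for immediate early genes, 0.18 for interferon, 0.071 for cholesterol, -0.30 for naive pluripotency and -0.074 for MYC targets. Fibroblast, immediate early and cholesterol genes were called with an estimated correlation too after the refitted background, with adjusted p from 0.016 to 0.035. The other lists were not called with Med12 knockdown. Members went both ways among endoderm genes (6 higher, 5 lower, median 0.02), unfolded protein and amino acid stress genes (4 higher, 6 lower, median -0.08), TGF-beta, NODAL and BMP genes (5 higher, 4 lower, median 0.16) and imprinted genes (5 higher, 2 lower, median 0.06). Igf2 rose by 0.76 (SE 0.04), with 1.33 for shMed12-1 and 0.20 for shMed12-2. The WNT target Notum, a WNT deacylase, fell by 1.18 (SE 0.16). The cell cycle inhibitor gene Cdkn2b rose by 0.78 within a cell cycle list at a median of -0.05. Medians were -0.10 for primed genes, 0.05 for mesoderm, 0.01 for neural genes, 0.00 for WNT targets, 0.03 for p53 targets, -0.03 for hypoxia, -0.06 for germ line, -0.07 for the 2-cell-like state and 0.06 for HOX genes.

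**Figure D2:**
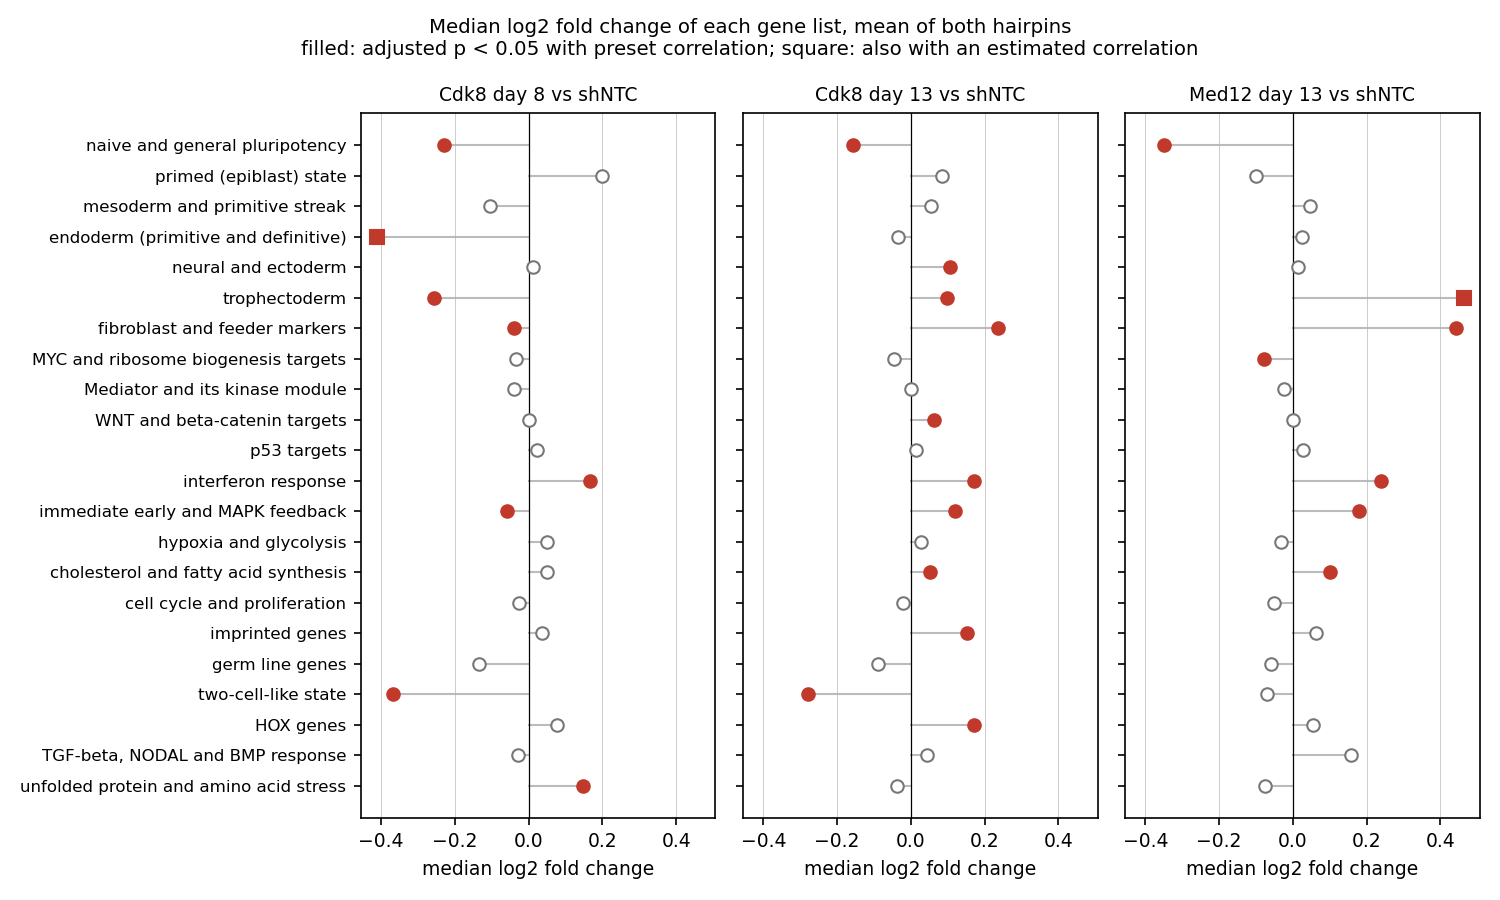
Median log2 fold change of each of the 22 gene lists for Cdk8 knockdown on day 8, Cdk8 knockdown on day 13 and Med12 knockdown on day 13, each the mean of both hairpins. The endoderm list stands at -0.41 on day 8 and the trophectoderm list at 0.46 with Med12 knockdown.

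**Figure D3:**
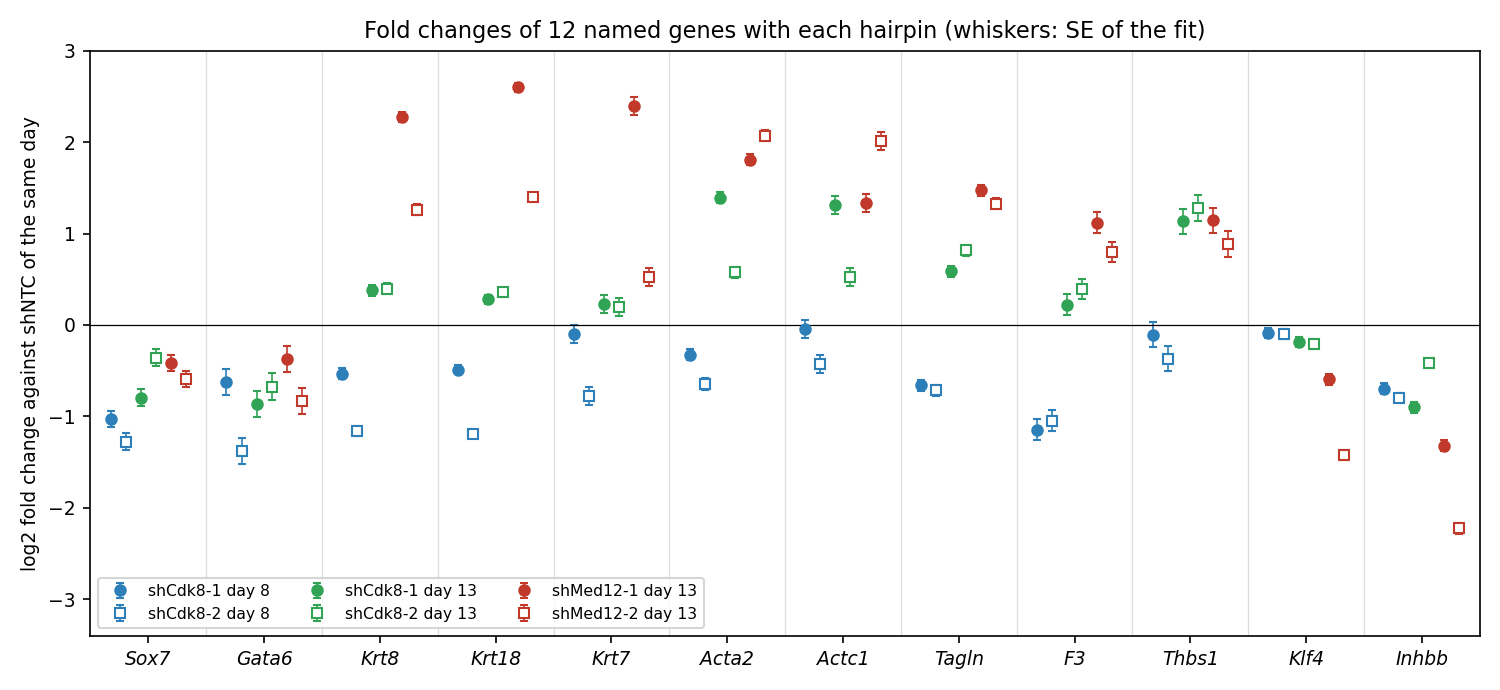
Log2 fold change against shNTC of the same day for 12 named genes with each of the 6 hairpin and day combinations, with whiskers of 1 standard error. Tagln lies below 0 with both Cdk8 hairpins on day 8 (-0.66 and -0.71), above 0 on day 13 (0.59 and 0.82) and highest with the Med12 hairpins (1.47 and 1.33).

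Cdk8 and Med12 knockdown were also set directly against each other on day 13. Lower with Cdk8 than with Med12 knockdown were Krt18 (-1.68, SE 0.04), Krt8 (-1.38), Rhox6 (-1.32), Krt7 (-1.25) and Krt20 (-1.20). Higher with Cdk8 than with Med12 knockdown were the neuronal gene Nsg2 (1.72, SE 0.25), Aass (1.39), Notum (1.38), Ccnd2 (1.30) and Skor1 (1.29), all 10 with adjusted p from 2.7e-17 to 4.5e-05. Klf4 (0.81) and Esrrb (0.53, and 0.33 after the refitted background) were higher too. Myc differed by 0.34, through shCdk8-2 (0.48 against shNTC): shCdk8-1 stood at -0.13, between the Med12 hairpins (-0.22 and -0.11). Sox2 and Zfp42 were not called, but were after the refitted background (0.40 and 0.30), Cdk19 was lower (-0.24), and Cdk8 and Med12 themselves differed by -0.75 and 1.04. In total 4073 genes differed, 1904 higher with Cdk8 knockdown and 2169 lower, 34 of them at least 2-fold, and 5068 after the refitted background, 2942 with slide as a block and 900 with median centring (485 higher, 415 lower); the authors' values gave 2896 higher and 2679 lower.

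Trophectoderm markers were lower with Cdk8 than with Med12 knockdown, 12 of 20 against 2 higher (12 and 2 adjusted over the list alone), with a median of -0.42 (adjusted p = 6.4e-07, and adjusted p = 0.034 with an estimated correlation). The 4 slides that held both knockdowns gave trophectoderm medians of -1.23, -1.10, -0.20 and -0.41. Endoderm genes were lower, 8 against 2 higher (9 and 4 adjusted over the list alone), with a median of -0.07 (adjusted p = 0.0017, and adjusted p = 0.034 with an estimated correlation). Krt18 and Krt8, the lowest genes named for this comparison, are on both lists, and the endoderm list was not tested without them. For 9 further lists, with adjusted p from 6.1e-06 to 0.042, the call was lost: adjusted p = 0.26 with an estimated correlation for MYC targets and adjusted p = 0.38 with an estimated correlation for the other lists. Fibroblast markers (median -0.15, 2 higher and 11 lower, 2 and 12 adjusted over the list alone), immediate early genes (-0.12, 5 and 14, 7 and 15 adjusted over the list alone) and 2-cell-like genes (-0.15, 0 and 6, 1 and 7 adjusted over the list alone) were lower with Cdk8 knockdown. Naive pluripotency genes (0.22, 11 higher and 0 lower, 13 and 0 adjusted over the list alone), primed genes (0.26, 7 and 1, 9 and 1 adjusted over the list alone) and neural genes (0.09, 11 and 1, 13 and 1 adjusted over the list alone) were higher. So were MYC targets (0.06, 12 and 3, 14 and 3 adjusted over the list alone), HOX genes (0.07, 5 and 0 in both counts, also adjusted over the list alone) and WNT targets (0.04, 12 and 5, 12 and 7 adjusted over the list alone), the last not called after the refitted background. There germ line genes were called (median -0.05), and neural and 2-cell-like genes also with an estimated correlation (adjusted p = 0.038 with an estimated correlation for both).

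The Cdk8 effect itself differed between the days in 531 genes, 325 with a higher and 206 with a lower value on day 13, 22 of them at least 2-fold. The count was 1265 after the refitted background, 158 with slide as a block, 21 with median centring and 304 to 820 when single arrays were left out. More genes had a lower than a higher value in the Cy5 channel alone (413 higher, 456 lower), in Feature Extraction's log ratios (613 and 636) and in the authors' values (619 and 645). Prss23 (1.67, SE 0.12), Acta2 (1.47, SE 0.08), Thbs1 (1.44), F3 (1.40) and Tagln (1.39) had the largest upward differences. Lefty2 (-1.03, SE 0.24), an antagonist of NODAL, Btbd17 (-0.96), Nupr1 (-0.66), Pck2 (-0.65) and Trp53i11 (-0.64) had the largest downward ones, all 10 with adjusted p from 4.2e-10 to 0.034. A further Prss23 probe stood at 0.13 on day 8 and 0.02 on day 13, one for Acta2 at -0.33 and 0.24, and one for Thbs1 at 0.10 and 0.52. Acta2 fell with both hairpins on day 8 (-0.33 and -0.65) and rose with both on day 13 (1.39 and 0.58), and Krt8 went from -0.53 and -1.16 to 0.38 and 0.40. The effect on Cdk8 itself did not differ by the test (-0.29, adjusted p = 0.12).

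Fibroblast and feeder markers had a higher Cdk8 effect on day 13 than on day 8, 10 of 37 with 1 lower (10 and 1 adjusted over the list alone). Their median difference was 0.28 (adjusted p = 3.9e-12, and adjusted p = 0.096 with an estimated correlation). Endoderm genes (median 0.22, 9 higher and 0 lower, 11 and 0 adjusted over the list alone, adjusted p = 8.2e-05 with an estimated correlation) and trophectoderm genes (0.21, 4 and 0, 5 and 0 adjusted over the list alone, adjusted p = 0.015 with an estimated correlation) had higher effects too. Immediate early genes likewise had a higher effect on day 13 (0.19, 11 and 0, 15 and 2 adjusted over the list alone, adjusted p = 0.015 with an estimated correlation), and stress genes of the unfolded protein and amino acid response a lower one (-0.18, 1 and 10, 2 and 19 adjusted over the list alone, adjusted p = 0.015 with an estimated correlation). Mesoderm genes (0.14, 2 and 0 in both counts, also adjusted over the list alone, adjusted p = 0.095 with an estimated correlation) and imprinted genes (0.09, 2 and 0 in both counts, also adjusted over the list alone, adjusted p = 0.10 with an estimated correlation) were called at the preset correlation. Fibroblast genes (adjusted p = 0.0025 with an estimated correlation) and imprinted genes (adjusted p = 0.0498 with an estimated correlation) were called in both tests after the refitted background. It also brought calls for primed, germ line and TGF-beta, NODAL and BMP genes at the preset correlation, the last also with an estimated one. With slide as a block the medians of the 7 lists were 0.34, 0.20, 0.15, 0.16, -0.15, 0.09 and 0.08 in the same order.

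Genes changed with both hairpins overlapped beyond independent lists. Such lists would share 142.8 higher and 121.8 lower genes for Cdk8 on day 8, 85.2 and 77.8 on day 13, and 260.5 and 235.4 for Med12. Across genes, which are not independent replicates, the fold changes of both hairpins had correlations of 0.39, 0.52 and 0.52, where unchanged groups against shared controls gave 0.50 each. Covariances were 0.017, 0.019 and 0.035 against 0.0069, 0.0069 and 0.0068 in the simulation, in which 0 genes were called with both. Cdk8 and Med12 knockdown on day 13 shared 473 genes changed with all 4 hairpins in the same direction, against 5 in opposite directions and 41.2 for independent lists. Their fold changes had a correlation of 0.66 against 0.67 in the simulation, and a covariance of 0.025 against 0.0068. Cdk8 knockdown on day 8 shared 282 genes with day 13 in the same direction (13 opposite, 24.4 independent) and 162 with Med12 knockdown (89 opposite, 49.6 independent). With 3 shNTC arrays per day the controls were not split, since that would leave a part with a single array. How much of the excess comes from shared controls is thus not known. With the shCdk8-1 arrays of day 8 set as the controls, 1318 genes were shared, against the 1142 seen. With the shMed12-1 arrays it was 2094 against 1927. For Cdk8 on day 13 the highest other split gave 924 against 945. For the first 2, the size of the overlap does not by itself show an effect of the targeted gene.

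The 24 arrays lay on 8 slides. Both shCdk8-1 groups and shMed12-1 shared no slide with shNTC of their day, so within-slide values exist for shCdk8-2 and shMed12-2 alone, from 1 slide on each day and 2 slides. Endoderm medians within those slides were -0.37 with shCdk8-2 on day 8 and -0.16 on day 13, and unfolded protein stress medians 0.21 and -0.04. Fibroblast medians were -0.19 and 0.14, and 0.33 and 0.36 with shMed12-2, and trophectoderm medians -0.14 and 0.15, and 0.06 and 0.05. For naive pluripotency the values were 0.03 and -0.09, and -0.18 and -0.32, for immediate early genes -0.14 and 0.12, and 0.16 and 0.20, and for interferon genes -0.01 and 0.15, and 0.21 and 0.20. All Med12 arrays lay at position 4 of their slides. The day 8 arrays lay at position 1, apart from shCdk8-2 replicate 3 at position 2. The other day 13 arrays lay at position 3, apart from shNTC replicate 1 at position 2. Day and position thus largely went together, also in the comparisons between the days. The Cy3 reference channel, which holds the same RNA on every array, gave 121, 4, 1, 0, 141 and 5 called genes by limma for the 6 hairpin comparisons, from shCdk8-1 on day 8 to shMed12-2. At an unadjusted p under 0.05 it gave 4253, 1639, 2344, 783, 3849 and 848, where chance alone would give a share of 0.05 of the 22394 genes. The largest counts, 4253, 3849 and 2344, belonged to shCdk8-1 on day 8, shMed12-1 and shCdk8-1 on day 13. These groups shared no slide with shNTC of their day, so differences between arrays or slides may add to their calls.

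**Figure D4:**
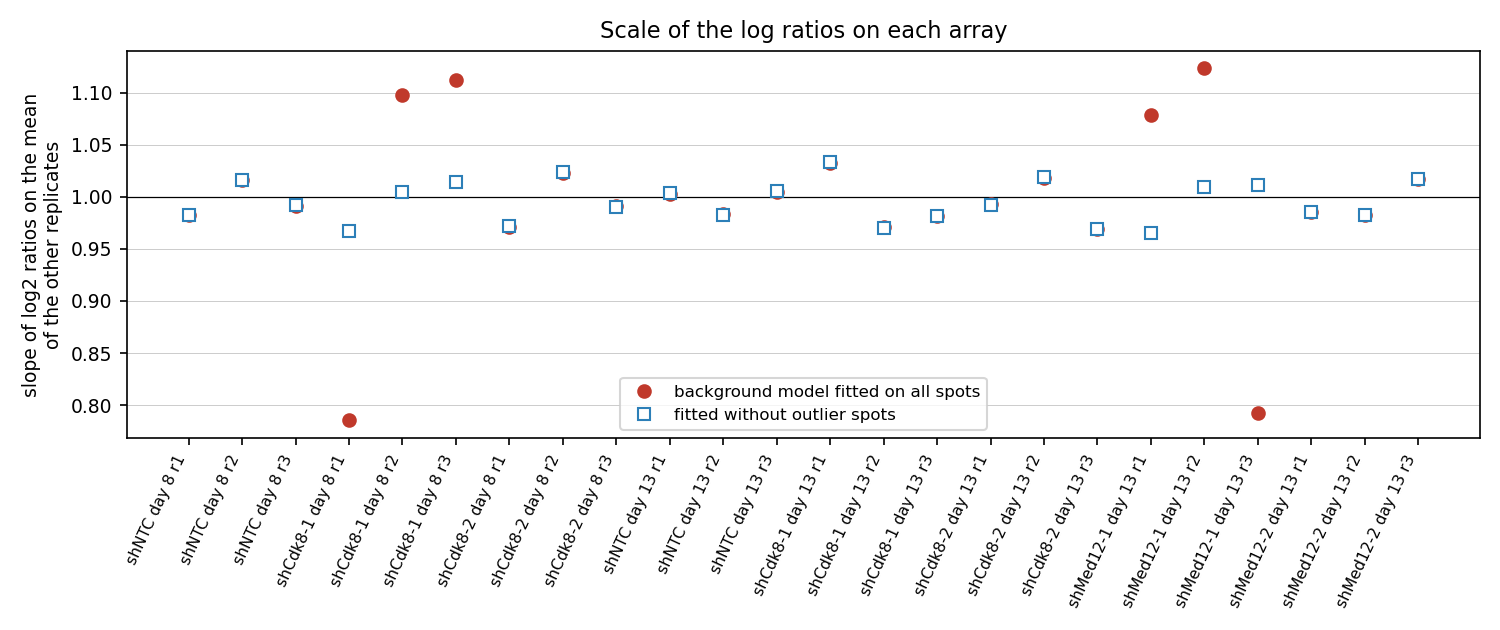
Slope of each array's log2 ratios on the mean of the other replicates of its group, over all genes tested, with the planned background model and with the refitted one. With the planned model 2 arrays stand at 0.79, below the other 22 at 0.97 to 1.12, and with the refitted one they stand at 0.97 and 1.01.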

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

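The tests of signal carried between channels, of the cell state on 2 arrays, of a lower reference signal and of the change in shNTC cells were chosen after the results were seen, as were the settings without 2 arrays and with the refitted background. Tests of the Cdk8 effect between days set apart 531 genes and, at the preset correlation, 7 gene lists, with median differences of 0.28 for fibroblast and feeder markers, 0.22 for endoderm, 0.21 for trophectoderm, 0.19 for immediate early genes, 0.14 for mesoderm, 0.092 for imprinted genes and -0.18 for unfolded protein and amino acid stress. With an estimated correlation 4 of them stayed called, and fibroblast, mesoderm and imprinted genes were lost (adjusted p from 0.095 to 0.10).

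The day difference of 3 lists may come from the hairpin arrays, from the shNTC arrays, or from both. The shNTC change made 12.9% of the mean difference of the fibroblast list (2000 resamples of its genes, -17.9% to 48.2%). From day 8 to day 13 the mean change there was 0.37 in the hairpin arrays and -0.05 in shNTC arrays. The resamples measure the spread between genes, not between the 3 shNTC arrays of each day, so they do not settle the source. For endoderm genes the share was 118% (32.6% to 256%), with a mean change of -0.32 in shNTC cells and -0.05 with the hairpins. For the stress list it was 75.1% (46.3% to 104%), with 0.14 in shNTC cells and -0.05 with the hairpins, so for these lists a change of the controls and a change of the Cdk8 effect cannot be told apart. A different response to Cdk8 loss over time stays open as a hypothesis for the fibroblast list, whose difference was not called with an estimated correlation (adjusted p = 0.096, and adjusted p = 0.0025 after the refitted background).

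Contractile genes and keratins rose together with both Med12 hairpins (18 genes, median 1.35). Fibroblasts or feeder cells among the ES cells would bring their matrix genes. These had a median of 0.38 (quartiles 0.26 and 0.57, 3 of 14 called), below the 1.19 of the contractile genes by more than their spread. Col1a1 stood at 0.99, Col3a1 at 0.74, Sparc at 0.59, Col1a2 at 0.36 and Thy1 at -0.18. In Cy5 brightness, matrix genes ranged from percentile 8.2 (Col5a2) to 92.7 (Sparc). Contractile genes ranged from 51.3 (Ankrd1) to 97.0 (Tagln), so the sets were not matched in brightness. Of these sets 13 matrix and 4 contractile genes are on the fibroblast list. For the set as a whole, a lower reference signal is argued against by the sample channel alone, with a median of 1.30, against -0.05 in the reference channel. For Krt18 and Krt8 the reference channel was lower, as given above, so it may make part of their rise. Array position cannot be told apart from Med12 knockdown, since 0 arrays at position 4 lacked a Med12 hairpin. Loss of Med12, as the design names it, stays open beside position and beside fibroblasts or feeder cells.

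Log ratios on shCdk8-1 day 8 replicate 1 and shMed12-1 day 13 replicate 3 were pulled toward 0, with slopes of 0.79. Signal carried from one channel to the other is argued against by the reference channel, where 310 genes high in ES cells shifted by 0.017 and -0.0082 after quantile normalization, and by 0.19 and 0.0093 before any correction (-0.45 to 0.21 on the other arrays); the planned background correction alone put them at 1.31 and 1.03. A different state of the cells would lower those genes in the sample channel, where the shift was -0.071, within the other 22 arrays (-0.12 to 0.13), and low signal is argued against by 71.2% and 60.3% of spots well above background, within the 48.9% to 76.1% of the others. On these arrays 4 and 7 spots, all with an outlier mark, had a local background far above the signal (lowest signal minus background of either channel from -6385.5 to -1718, against -41.5 to -3 elsewhere), and the fitted background SD was 42.8 to 138 against 0.43 to 3.14. With the background model fitted without marked spots the lower slope was 0.967, in the range of the other arrays (0.965 to 1.03), which is in line with a few spots upsetting the background model, a candidate explanation that other correction methods also bear out, with slopes of 0.97 and 1.04 for Feature Extraction's log ratios.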

How the results depend on the processing

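The settings without 2 arrays (shCdk8-1 day 8 replicate 1 and shMed12-1 day 13 replicate 3) and with the refitted background were chosen after the data were seen. Leaving single arrays aside, 157 counts of genes or lists stayed within 1.5 times, 27 were higher and 23 lower. Of the named genes 4042 values kept their side of the threshold, 426 lost the call and 30 gained it. A further 2 reversed, with a call in the planned fit or in the alternative. Values called in neither fit could change direction and were counted as kept. Of the list values 867 were the same in this sense, 47 gained and 10 lost the call. Most lost gene calls came from median centring (158) and slide as a fixed block (117). Quantile normalization between arrays acts on brightness alone and moved no ratio. Between 48.9% and 76.1% of spots were well above background, and whether signal accounts for other lost calls was not tested.

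Cplx2 with Cdk8 knockdown on day 8 reversed to -0.018, not called, and Zfp42 in the day difference to -0.33, both in the Cy5 channel alone, and the cause was not tested.

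With median centring in place of loess the hairpin counts, from shCdk8-1 on day 8 to shMed12-2, were 829 (645 higher, 184 lower), 322 (126, 196), 347 (138, 209), 203 (70, 133), 1319 and 1104 (320, 784). Both hairpins changed 90, 49 (14, 35) and 389 (138, 251), Cdk8 against Med12 gave 900 and the day difference 21, lists called on day 8 were 13, and Cdk8 with shCdk8-2 on day 8 was -0.35, not called; the cause was not tested. The shift of the all-gene median was at most 0.093. With slide as a fixed block, which takes 7 degrees of freedom, they were 830 (534, 296), 1379, 890, 1247 and, for shMed12-1, 1513 (947, 566), with 310 (206, 104), 279 and 708 for both hairpins and 158 (117, 41) for the day difference. As a random block slide gave 3771, 3101, 2826, 2547, 5587 and 3922.

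Without background correction shCdk8-2 on day 8 gave 4743, both groups on day 13 4318 and 4121, both Cdk8 hairpins 1893 and 1696, and the day difference 1240. Feature Extraction's log ratios gave 4752, 4766, 4405, 1883, 1827 (833, 994) and 1249 (613, 636), with 1225 higher and 1470 lower for both Med12 hairpins. The authors' values gave 4783, 4807, 4418, 1900, 1841 (839, 1002) and 1264 (619, 645), with 1238 higher and 1484 lower for Med12. The refitted background gave 3895 for shCdk8-2 on day 13, 1725 and 1558 for both Cdk8 hairpins and 1265 for the day difference. Leaving out both arrays gave 1523 for both Cdk8 hairpins on day 13 and 1254 for the day difference. The Cy5 channel alone gave 869 (413, 456) for the day difference, and 1511 higher and 2140 lower, 1169 and 1789, 471 and 727, and 871 and 1247 for the Cdk8 hairpins on day 13, both of them, and both Med12 hairpins. With no filter the day difference was 351, over 33324 genes; the cause was not tested. With only the groups compared in the fit, shCdk8-1 on day 8 gave 1471, shMed12-2 6149 and both Cdk8 hairpins on day 8 497; the cause was not tested.

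Replicate numbers gave no sign of a pairing of the arrays. Over 84 pairs with the same number the median correlation of deviations was -0.016, and 17 were over 0.1. Over 168 pairs with different numbers the median was 0.0077, and 36 were over 0.1. Of 24 arrays, 5 correlated best with their own number. These values cannot exclude that arrays with the same number were handled together. With the number as a replicate block the counts were 3673, 3066, 2737, 2546, 5440 and 3898, both hairpins 1117, 918 and 1889, Cdk8 against Med12 4018 and the day difference 471, and 8, 11 and 7 lists were called.

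Leaving out each array in turn gave 2527 to 3634 and 2170 to 2612 on day 8, 1941 to 2263 and 1610 to 2262 on day 13, and 3987 to 5559 and 2944 to 3231 for Med12. Both hairpins gave 754 to 1187, 570 to 857 and 1328 to 1841, Cdk8 against Med12 3433 to 4064, and lists 7 to 10, 11 to 12 and 7 to 7. Cdk8 ranged from -0.79 to -0.65, -0.35 to -0.26, -1.01 to -0.91 and -0.68 to -0.58, Med12 from -1.06 to -0.95 and -0.94 to -0.81. The day difference ranged from 304 to 820: 341, 329 and 319 without shNTC day 8 replicates 1, 2 and 3, 309, 304 and 322 without shNTC day 13 replicates 1, 2 and 3, and 820 without shCdk8-1 day 8 replicate 1. Both Cdk8 hairpins gave 759 and 754 without shNTC day 8 replicates 1 and 2, 570 and 617 without shNTC day 13 replicates 1 and 3, and shCdk8-2 on day 13 gave 1610 without shNTC day 13 replicate 1.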

Other observations

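The comparison of shNTC cells between the days and the genes named from it were chosen after values had been seen, and the counts of other splits were planned. From day 8 to day 13, 3936 genes differed between the shNTC arrays (1918 higher, 2018 lower, 133 at least 2-fold). The shNTC arrays of day 8 lay at position 1 of their slides and those of day 13 at positions 2, 3 and 3. A change of the cells and array position therefore cannot be told apart in this comparison. Genes of the 2-cell-like state fell, 11 of 15 with 0 higher (12 and 0 adjusted over the list alone), with a median of -0.71 (adjusted p = 9.1e-07, and adjusted p = 0.059 with an estimated correlation). Zscan4c, a marker of that state, fell by 1.16 (SE 0.28), P4ha2 by 0.93 (SE 0.07) and Tcstv1 by 0.71 (SE 0.16). Endoderm genes fell, 15 of 37 with 5 higher (17 and 7 adjusted over the list alone), with a median of -0.27 (adjusted p = 5.4e-04, and adjusted p = 0.037 with an estimated correlation). The forkhead gene Foxa2 fell by 1.34 (SE 0.09), Gata6 by 1.30, Sox7 by 0.76 and Sox17 by 0.72, while Krt8 and Krt18, which are on that list too, rose by 0.92 (SE 0.06) and 0.70 (SE 0.05).

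Trophectoderm genes rose with a median of 0.21, 6 of 20 with 0 lower (6 and 0 adjusted over the list alone; adjusted p = 1.3e-05, and adjusted p = 0.059 with an estimated correlation), and Cdx2, a factor that specifies trophectoderm, rose by 1.95 (SE 0.30). Immediate early genes rose, 17 of 37 with 2 lower (20 and 3 adjusted over the list alone), with a median of 0.20 (adjusted p = 2.1e-06, and adjusted p = 0.059 with an estimated correlation) and Dusp6 at 0.68 (SE 0.06). Stress genes of the unfolded protein and amino acid response rose, 15 of 46 with 4 lower (17 and 5 adjusted over the list alone), with a median of 0.11 (adjusted p = 5.4e-04, and adjusted p = 0.16 with an estimated correlation), among them Ddit3 (0.78, SE 0.10) and Herpud1 (0.49). The interferon-induced gene Gbp2 rose by 1.96 (SE 0.08) and Tagln by 1.21 (SE 0.06), and Klf4 fell by 0.33 (SE 0.06). WNT targets (0.14), p53 targets (0.08), interferon genes (0.08) and cholesterol genes (0.11) had higher medians with adjusted p from 0.0038 to 0.023. Cell cycle genes (-0.08, adjusted p = 0.0018) and naive pluripotency genes (-0.12, adjusted p = 0.011) had lower ones. All 6 lost the call, with adjusted p = 0.12 with an estimated correlation for WNT and p53 targets, adjusted p = 0.53 with an estimated correlation for interferon and naive genes, adjusted p = 0.34 with an estimated correlation for cholesterol and adjusted p = 0.093 with an estimated correlation for cell cycle. After the refitted background 15 lists were called, with mesoderm, neural, germ line and HOX genes added, and 7 with an estimated correlation: endoderm, trophectoderm, immediate early, 2-cell-like, stress, p53 and cholesterol genes.

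Other splits of the arrays were refitted for each count. For each hairpin, 3 arrays against 3 make 10 splits, too few for a share under 0.05, and in each case 1 split, the real one, gave as many genes: 3775 and 3136 on day 8, 2822 and 2587 on day 13 and 5567 and 3988 with Med12 hairpins. The highest other split gave 1 gene for shCdk8-1 on day 8 and 0 for the other 5. Of 100 splits, 2 gave as many genes changed with both Cdk8 hairpins on day 8 as the 1142 seen (highest other 1318), 1 as many on day 13 (945, highest other 924) and 2 as many with both Med12 hairpins (1927, highest other 2094). For Cdk8 against Med12 it was 1 (4073, highest other 593) and for the day difference 2 (531, highest other 819). These shares are under 0.05, which argues against a random grouping of the arrays for these 5 counts. The splits show that arrays of a group resemble each other. They cannot tell knockdown from slide or other differences between groups. The higher splits followed groups, with the shCdk8-1 arrays of day 8 or the shMed12-1 arrays set as the controls, and for the day difference the shCdk8-2 arrays of day 8. After the refitted background the counts were 1725 (highest other 1878), 1558 (1513), 2436 (2536), 5068 (1241) and 1265 (1660).

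Chance could not be excluded for the number of lists called on day 8 with Cdk8 knockdown, where 45 of 84 splits gave 8 or more (highest 13), or with Med12 knockdown, where 54 of 84 gave 7 or more (highest 12). On day 13 with Cdk8 knockdown 1 of 84 splits gave 11 or more at the preset correlation (highest other 9). That argues against a random grouping of the arrays for that count, but cannot tell knockdown from slide. With an estimated correlation 0 of 22 lists were called there. With the refitted background 2 of 84 splits gave 11 or more on day 8, 1 of 84 gave 13 or more on day 13, and 35 of 84 gave 7 or more for Med12.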
